A study of Mus musculus with 4 samples.

How the data were processed

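Transcriptomes were measured in 4 libraries of muscle stem cells, 2 WT and 2 NDRG1 cKO, grouped by the genotype and replicate in their titles. Per the labels' protocols, mice received 2 mg tamoxifen per intraperitoneal injection, cDNA was made from 2 ng of total RNA with a SMARTer low-input kit, and libraries were made from 150 pg of amplified cDNA with a Nextera XT kit.

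The deposited table holds raw gene counts that the authors made with featureCounts 1.5.1, per the file headers. Per the file headers, fragments were counted as read pairs over exons and summed by gene identifier, both ends had to be aligned, chimeric pairs were excluded, and no strand option was set. Per the file headers, the counted alignment files came from a STAR output directory. The submitters' processing notes also name Trim Galore 0.4.2 and STAR, the latter without a version, and the builds GRCm39 and mm9 without saying what each was used for. Of the gene identifiers in the table, 52083 were also in a GRCm38 annotation (GENCODE), and 1494 of these (2.87%) had the same start and end there, so GRCm38 coordinates were not used.

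The table was read with Python 3.11.15 and pandas 2.3.3. It has 55416 rows, each with its own gene identifier, and no row without a gene. All 4 value columns were matched to samples by the library name in the column header. Symbols came from a reference table of Ensembl identifiers, which named 52083 of the identifiers and left 3333 unnamed. Every value in the 4 columns was 0. The reading step was tested on 200 rows with planted counts and returned the planted total of each library. Single rows were not compared, and the test used the same match of columns to samples, so it does not check that match.

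The planned test, fixed before the data were examined, was edgeR's quasi-likelihood test of NDRG1 cKO against WT with TMM normalization, a filter on low counts and a Benjamini-Hochberg adjusted p under 0.05, followed by camera on the fixed gene lists with a preset correlation of 0.01. It was not run. With edgeR 4.0.16 under R 4.3.3, the filter on low counts and CPM values could not be computed because 0 libraries had a total above 0. The rule for genes to be named by their p-values had nothing to act on. The genes named are Ndrg1 and those the rule lists whatever their p, together with Actb, Gapdh, Eef1a1, Rplp0 and mt-Co1, which every cell uses, named after the values were seen.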

Results

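RNA sequencing was performed on muscle stem cells of aged mice to ask how loss of NDRG1 in these cells alters their transcriptome. NDRG1 (N-myc downstream regulated 1) is a cytoplasmic protein linked to growth arrest and stress responses. Muscle stem cells, also called satellite cells, are the resident cells that regenerate skeletal muscle fibres and are marked by the transcription factor PAX7. In the conditional knockout (NDRG1 cKO), a tamoxifen-inducible Cre recombinase expressed from the Pax7 locus removes a floxed Ndrg1 gene in these cells. The series holds 4 libraries in 2 groups, 2 labelled WT and 2 labelled NDRG1 cKO. The labels do not say whether the libraries of a group came from separate animals.

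No gene had a measured expression level in the count table. Each of the 4 libraries was listed at 0 for all 55416 genes, so the total count per library was 0 in WT replicates 1 and 2 and in NDRG1 cKO replicates 1 and 2. The highest count of any gene in any library was 0. The genes at 0 lay on all 39 chromosomes and other sequences in the table, including the 37 genes of the mitochondrial genome. A library total of 0 gives no depth, so no share of counts, no upper limit on expression and no confidence interval could be computed.

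The deleted gene, Ndrg1 (ENSMUSG00000005125), was listed at 0 in both WT and both NDRG1 cKO libraries. The table places Ndrg1 on the minus strand of chromosome 15 between positions 66801167 and 66841489, with a summed exon length of 6596 bp. The file does not name the genome build of these positions. Because the WT libraries were also at 0, the values do not check the genotype labels. The paralogs Ndrg2, Ndrg3 and Ndrg4 were likewise listed at 0 in every library.

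Genes of the studied cell type, of its differentiation and of proliferation were listed at 0 as well. These included Pax7 and Myf5, which mark muscle stem cells, Myod1 and Myog, which drive myogenic commitment and differentiation, and the proliferation gene Mki67. The cell cycle inhibitor gene Cdkn1a, the kinase gene Mtor and the stress-induced inhibitors of its pathway Ddit4 and Sesn2 were also at 0 in all 4 libraries. Genes that every cell uses were no different. Actb, Gapdh, Eef1a1, Rplp0 and the mitochondrially encoded mt-Co1, which were chosen after the values were seen, were at 0 in each library. These entries therefore state only that a gene is listed at 0, not that it was unexpressed.

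Of 894 genes in 39 gene lists fixed before the data were examined, 876 were found in the table, and 0 of these had a count above 0 in any library. The lists covered stem cell identity, Notch signalling, myogenic differentiation, cell cycle, amino acid, sterol and ribosome genes, p53 targets, apoptosis, mTOR pathway components, interferon response and markers of other cell types in muscle. For example, all 26 genes of the satellite cell identity list, all 33 mTOR and PI3K pathway components and all 78 cytosolic ribosomal protein genes were found and listed at 0.

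The comparison that the design implies, NDRG1 cKO against WT, could not be made from these values. No fold change, error, p-value or count of changed genes is given, because a table of zeros holds no difference between libraries and no spread between replicates. This is a property of the table and gives no evidence for or against a difference between the genotypes.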

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

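The number of genes with a count above 0 was 0 in all 4 libraries together, 0 when each library was left out in turn, and 0 when mitochondrially encoded and ribosomal protein genes were left out. These values say nothing about stability, because no setting can move a table of zeros. Further alternatives were listed before the data were examined and were not run, since each needs a library total above 0: the RLE and upper quartile normalizations, the other filters on low counts, DESeq2, limma-voom, robust edgeR, other thresholds, and the list tests with an estimated correlation or with fry. No paired analysis was possible because every count was 0, and a model with the replicate number as a block has no values to fit. Apart from the zeros, the titles give each library a replicate number but do not say whether libraries with the same number belong together.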

Other observations

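The zeros covered the whole table. Of the 55416 genes, 55359 were on sequences named with the prefix chr and the rest on sequences with GL or JH names. Of the 39 sequences, 0 held a gene with a count above 0. The cause was not tested, since alignments and reads were not analysed here.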
